A study of Rattus norvegicus with 12 samples.

How the data were processed

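Expression was measured in dorsal root ganglia of 12 rats, 4 each given vehicle, cisplatin, or cisplatin with CYM-5478. Total RNA was depleted of ribosomal RNA and made into directional libraries. The authors deposited 1 table of FPKM per transcript and sample, and their notes name bcl2fastq 2.20, FastQC, Bowtie2 2.0.6, STAR 2.7.8a and DESeq2 with the rat build Rnor_6.0, without a role or order. The program that gave the FPKM and any filter applied are not stated in the sources used. The table as used here holds 30275 transcripts of 25252 genes and is smaller than its listed size, so some transcripts may be missing from it. Read counts were not used, so absolute depth is unknown and no counting interval is given. Sample titles and descriptions number the rats differently, and the description numbers, 1 to 4 in each group, are used as replicate numbers.

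FPKM of the transcripts of a gene were summed, and each library was scaled by the median ratio to the geometric mean over genes with a mean of 1 FPKM or more (factors 0.9983 to 1.012). Genes with a mean of 0.5 FPKM or more were tested, 16753 in all, on log2(FPKM + 0.5). Limma 3.58.1 in R 4.3.3 fitted the 3 groups to all 12 libraries (9 residual degrees of freedom, variance trend), and Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. Groups of genes were tested by limma's camera with a preset correlation of 0.01, adjusted over the 34 lists that had 5 or more tested genes, and again with the correlation estimated for each list and with the rotation test fry. The lists held 676 symbols, of which 641 matched by symbol, 12 by synonym and 23 not at all. A list score is the mean over its genes of the log2 value minus the vehicle mean. Group differences of single measures were tested by two-sided exact permutation, for which 0.0286 is the smallest p with 4 against 4. Genome coordinates are not given because the annotation of the authors' build was not used here.

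The gene lists, the tests of genes and lists apart from the rotation test, and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the 12 largest rises and 12 largest falls among genes past the threshold whose libraries did not overlap. Where fewer than 10 genes passed it took the 8 smallest p in each direction. It added up to 4 genes of smallest p from each list discussed, and S1pr1 to S1pr5, Atf3 and Cdkn1a. Genes with clone-based names or no clear identity are not described, and some other genes and lists are not analysed here. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 2 FPKM, no scaling, TPM, quantile normalization, protein-coding genes, single transcripts, array weights, robust variances, fits of 8 libraries, replicate numbers as a block, and each library left out in turn. Chosen after seeing the data were the rotation test, the pan-neuronal score as a covariate, and leaving out cisplatin replicates 2 and 3 (highest muscle scores) or CYM-5478 replicates 2 and 3 (extreme neutrophil scores). The tests of explanations, the splits for the 3 counts of genes, the gene family tests and the tests of both cisplatin groups against vehicle, apart from the splits for the latter, were also added then. The workflow was tested on simulated log2 values for 12 libraries, drawn with the mean and spread of each gene. Changes were added to the simulated cisplatin libraries, in genes that were not low. For cisplatin against vehicle it called 70 of 100 genes changed 1.5-fold and 87 of 100 changed 2-fold, with 10 false among 167 calls. Genes were simulated as independent of each other, so these rates need not hold for the real libraries.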

Results

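Dorsal root ganglia, which hold the cell bodies of sensory neurons, were taken from 12 Sprague Dawley rats in 3 groups of 4, and rRNA-depleted total RNA was sequenced. Vehicle rats had saline with 0.1% Tween 20 and 1% DMSO. The cisplatin group was given this platinum chemotherapy drug at 3 mg/kg into the peritoneum on days 0, 7 and 14. A further group had the same cisplatin with CYM-5478, an agonist of the sphingosine 1-phosphate receptor S1P2, daily from day -1 to day 20. The sample labels give its dose as 0.1 mg/kg and the treatment protocol as 1 mg/kg. No group had CYM-5478 without cisplatin, so its effect by itself cannot be separated from one on the response to cisplatin. The series asks whether activating S1P2 protects against the peripheral neuropathy that cisplatin causes. Values are FPKM (fragment counts scaled by transcript length and library size), summed over the transcripts of a gene. Fold changes are on the log2(FPKM + 0.5) scale, which understates changes of low genes.

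The deposited FPKM of a library summed to 593 to 676 in units of 1000 FPKM. This sum was higher in cisplatin libraries (657 ± 14.8, SD, n = 4) than in vehicle libraries (602 ± 7.06, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). With CYM-5478 it was 606 ± 14 (exact permutation p = 0.0286 against cisplatin and 0.8 against vehicle). The 10 genes of highest mean, among them mitochondrial transcripts, hemoglobin and myelin genes, held 13.8% of the sum in vehicle, 16.4% in cisplatin and 13.3% with CYM-5478. Spearman correlations between libraries over the tested genes ran from 0.963 to 0.987, and the first 2 principal components held 20.8% and 13.2% of the variance. Absolute read depth is unknown. The steps between low values put CYM-5478 replicate 2 at 1.5 times the depth of vehicle replicate 1 and the other libraries at 0.9 to 1.2 times. Markers of other tissues, scored as the mean log2 difference from the vehicle mean, varied between rats. The skeletal muscle score was 1.69 in cisplatin replicate 2 and 0.75 in replicate 3. The neutrophil and granulocyte precursor score was 1.60 in CYM-5478 replicate 2 and -1.42 in replicate 3.

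Genes of sensory neurons were lower in ganglia of cisplatin rats than in those of vehicle rats, the comparison that asks what cisplatin changed in this tissue. Uchl1, an abundant ubiquitin hydrolase of neurons, fell from 1150 ± 137 to 726 ± 122 FPKM (SD, n = 4 each, log2 change -0.67, SE 0.13), and Tubb3, a tubulin of neurons, from 838 ± 143 to 504 ± 98.8 (-0.74, SE 0.15). Pou4f1, a transcription factor of sensory neurons, fell by 0.80 (SE 0.13) and Eno2, the neuronal enolase, by 0.53 (SE 0.11) on the log2 scale. Among 18 pan-neuronal genes, 14 fell, 0 rose and 4 did not pass the test, and 17 fell when adjusted over the list alone. The list was lower as a group (median log2 change -0.62, limma camera adjusted p = 1.77e-10, adjusted p = 0.507 with an estimated correlation). Over all 16753 genes tested, 1794 passed limma's test at an adjusted p under 0.05, with 457 higher and 1337 lower in cisplatin (25.5% higher), and the smallest adjusted p was 0.0124. Rescaled to TPM, where the sum of FPKM enters, 3274 genes passed, 116 higher and 3158 lower (3.54% higher). The 4 cisplatin and 4 vehicle libraries did not overlap for 18.3% of genes, against 2.86% by chance. The count was 3 without vehicle replicate 2, 1169 without vehicle replicate 3, 776 without cisplatin replicate 1 and 0 without cisplatin replicate 4 (lowest adjusted p 0.0516, with 4082 genes at an unadjusted p under 0.05). With the 8 libraries of the 2 groups alone it was 1019, and with the title numbers as a block 0 (2535 at an unadjusted p under 0.05). With the pan-neuronal score as a covariate, chosen after seeing the data, limma called 0 genes (1321 at an unadjusted p under 0.05). That score itself differed between these groups, so such a fit also takes out part of any group difference. All 53 called genes named for this comparison lost their call without vehicle replicate 2 or cisplatin replicate 4, and leaving out any other library ended the call of 1 to 23 of them.

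**Figure D1:**
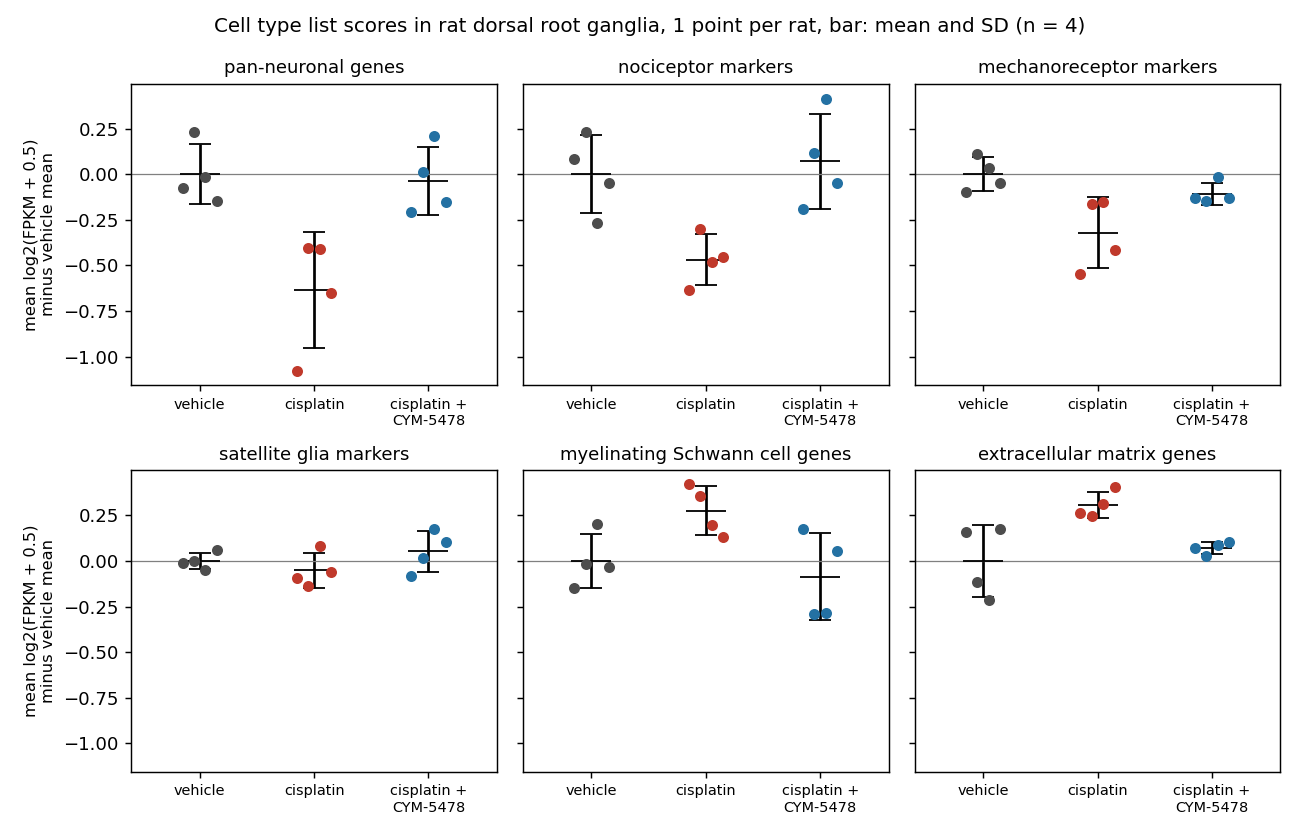
Scores of 6 cell type lists in each of the 12 libraries (y axis: mean over list members of log2(FPKM + 0.5) minus the vehicle mean; x axis: treatment group; points: rats; bars: mean and SD, n = 4). Pan-neuronal scores averaged 0 in vehicle, -0.64 in cisplatin and -0.04 with CYM-5478, and extracellular matrix scores 0, 0.31 and 0.07.

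Both pain-sensing and touch-sensing neuron markers were among the genes that fell with cisplatin. Trpa1, a channel for irritants, fell from 12 ± 1.18 to 7.68 ± 1.09 FPKM (SD, n = 4 each, log2 change -0.62, SE 0.10). Prdm12, a transcription factor of pain-sensing neurons, fell by 0.82 (SE 0.16) and Scn9a, a sodium channel needed for pain, by 0.60 (SE 0.12) on the log2 scale. Of 22 nociceptor markers 9 fell, 0 rose and 13 did not pass, with 15 lower adjusted over the list alone (limma camera adjusted p = 2.66e-08, adjusted p = 0.507 with an estimated correlation). Scn8a and Scn1a, sodium channels of large neurons, each fell by 0.83 (SE 0.17 and 0.18), Kcnc1, a fast potassium channel, by 0.73 (SE 0.16) and Ntrk2, the receptor for brain-derived neurotrophic factor, by 0.44 (SE 0.086). These are 4 of the 5 of 20 mechanoreceptor and proprioceptor markers that fell. In that list 0 rose, 15 did not pass and 7 were lower adjusted over the list alone (camera adjusted p = 2.84e-04, adjusted p = 0.507 with an estimated correlation). In the list of genes that respond to nerve injury, 4 of 21 fell, 0 rose and 17 did not pass, also 4 lower adjusted over the list alone. They were Nefl, a neurofilament (log2 change -0.89, SE 0.22), Cacna2d1, a calcium channel subunit that gabapentin binds (-0.47, SE 0.095), Lifr, a cytokine receptor (-0.29, SE 0.082), and Hspb1, a small heat shock protein (-0.50, SE 0.12). That list did not pass as a group (camera adjusted p = 0.124, adjusted p = 0.607 with an estimated correlation). Atf3, an injury-induced transcription factor, was at 9.72 ± 0.942 FPKM in vehicle and 11.6 ± 2.61 in cisplatin (SD, n = 4 each, limma adjusted p = 0.371). The pan-neuronal score was 0.64 lower in the same libraries. With it as a covariate the mean of the nociceptor list went from -0.469 to -0.06 (camera adjusted p = 0.0646) and that of the mechanoreceptor list from -0.319 to -0.004 (0.755), which ended both calls. Without vehicle replicate 2 or cisplatin replicate 4, where 3 and 0 genes passed in all, none of the genes named here kept its call.

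Some nuclear-encoded energy genes and chaperone genes fell with cisplatin, while Cryab rose and satellite glia markers went both ways. Nuclear-encoded oxidative phosphorylation genes were lower as a list (median log2 change -0.11, camera adjusted p = 0.00731, adjusted p = 0.607 with an estimated correlation), with 5 of 28 lower, 0 higher and 6 lower adjusted over the list alone. Ndufs1 of complex I fell by 0.33 (SE 0.069), Atp5g1 of the ATP synthase by 0.36 (SE 0.082) and Cox5a of cytochrome oxidase by 0.33 (SE 0.084). Hsp90aa1, an abundant chaperone, fell from 502 ± 47.4 to 387 ± 41.3 FPKM (SD, n = 4 each), and Bag3, a co-chaperone of Hsp70, by 0.39 (SE 0.11) on the log2 scale, while Cryab, a small heat shock protein, rose by 0.41 (SE 0.11). Of 10 heat shock genes 3, with Hspb1, fell, 1 rose and 6 did not pass, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0406, adjusted p = 0.51 with an estimated correlation). Among 13 satellite glia markers, the potassium channel gene Kcnj10 (log2 change -0.50, SE 0.083), Aldoc, a glycolytic aldolase (-0.45, SE 0.11), and Ptprz1, a receptor phosphatase (-0.35, SE 0.096), fell, and Glul, glutamine synthetase, rose (0.20, SE 0.059). The other 9 did not pass, and adjusted over the list alone 3 fell and 2 rose (camera adjusted p = 0.676, adjusted p = 0.798 with an estimated correlation). The pan-neuronal score was 0.64 lower in the same cisplatin libraries (-0.64 ± 0.32 against 0 ± 0.16, SD, n = 4 each). The heat shock call of camera ended without vehicle replicate 2 (adjusted p = 0.0772), vehicle replicate 4 (0.101) or cisplatin replicate 1 (0.0688), and the oxidative phosphorylation call without cisplatin replicate 1 (0.095). The mean of the latter list, -0.1, was -0.057 there and -0.064 without vehicle replicate 2. With the pan-neuronal score as a covariate the means of the heat shock and oxidative phosphorylation lists turned, from -0.159 to 0.005 (adjusted p = 0.988) and from -0.1 to 0.082 (0.0495), and with array weights the heat shock call ended (0.051). No gene call of this paragraph stood without vehicle replicate 2 or cisplatin replicate 4, where 3 and 0 genes passed.

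Connective tissue, ribosome, myelin, vessel and mitochondrially encoded genes were higher as lists in the cisplatin ganglia by camera at its preset correlation. Exact permutation p of the list scores was 0.0286 for matrix, 0.0857 for myelin and 0.171 for endothelial genes. The rotation test ended the myelin (adjusted p = 0.131), endothelial (0.165) and mitochondrially encoded (0.0676) calls and kept the matrix and ribosomal ones. Collagen genes Col6a1 (99.1 ± 13 to 137 ± 11.4 FPKM, SD, n = 4 each, log2 change 0.47, SE 0.087), Col5a2 (0.42, SE 0.060) and Col6a2 (0.33, SE 0.076) rose. Of 20 fibroblast and extracellular matrix genes 6 rose, 0 fell and 14 did not pass, with 13 higher adjusted over the list alone (camera adjusted p = 1.13e-07, adjusted p = 0.507 with an estimated correlation). Cytosolic ribosomal protein genes were higher as a list, with 6 of 27 higher, 0 lower and 20 higher adjusted over the list alone (camera adjusted p = 2.57e-09, adjusted p = 0.507 with an estimated correlation). Rpl5 rose by 0.27 (SE 0.056) and Rpsa by 0.25 (SE 0.069), although near-identical copies of ribosomal protein genes make their single values uncertain. Myelinating Schwann cell genes were higher as a list (median 0.29, camera adjusted p = 7.82e-05, adjusted p = 0.51 with an estimated correlation), but 1 of 22 passed by itself, also 1 adjusted over the list alone: the scaffold gene Mpp6 (0.30, SE 0.064). Egr2, a transcription factor that drives myelination, was at 29.2 ± 6.30 and 42.7 ± 8.67 FPKM (SD, n = 4 each, limma adjusted p = 0.0835). Of 16 endothelial markers, Cldn5, a tight junction protein of vessels, rose (0.34, SE 0.091) and 15 did not pass, the same count as adjusted over the list alone. The list passed (camera adjusted p = 0.00731, adjusted p = 0.537 with an estimated correlation), though not without vehicle replicate 3 (adjusted p = 0.0657, mean 0.118 in place of 0.182). Mitochondrially encoded genes were higher as a list (median 0.44, camera adjusted p = 6.22e-04, adjusted p = 0.51 with an estimated correlation, 0.554 after quantile normalization), with 0 of 11 past the threshold by themselves or adjusted over the list alone. Quantile normalization took the mean of that list from 0.395 to 0.075. Mt-nd2, a subunit of complex I, was at 899 ± 169 and 1490 ± 458 FPKM (SD, n = 4 each, limma adjusted p = 0.0629). Pan-neuronal scores were lower by 0.64 in these libraries. With that score as a covariate the means of the myelin and endothelial lists went from 0.276 to 0.053 (adjusted p = 0.737) and from 0.182 to 0.071 (0.458), which ended both calls. The gene calls ended without vehicle replicate 2 or cisplatin replicate 4, where 3 and 0 genes passed.

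Immune and hormone-responsive genes were higher as lists by camera at its preset correlation, with few single genes past the threshold. None of these lists passed the rotation test (adjusted p = 0.0537 to 0.405). Macrophage markers had 0 of 17 past it, also adjusted over the list alone (median log2 change 0.30, camera adjusted p = 1.47e-04, adjusted p = 0.507 with an estimated correlation). Fcer1g, an Fc receptor subunit, stood at 27.8 ± 5.66 FPKM in vehicle and 43.8 ± 11.2 in cisplatin (SD, n = 4 each, limma adjusted p = 0.0644). Among 22 cytokine and acute inflammation genes, Tnfaip3, an inhibitor of NF-kB signalling, and Vcam1, an adhesion molecule, rose by 0.30 (SE 0.080) and 0.29 (SE 0.084) and 20 did not pass. Adjusted over the list alone 0 rose and 0 fell by limma, and the list passed (camera adjusted p = 0.0302, adjusted p = 0.51 with an estimated correlation). Antigen presentation genes (0 of 15 by themselves, also adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.51 with an estimated correlation) were higher as a list. B2m, the light chain of MHC class I, was at 231 ± 21.7 and 279 ± 33.3 FPKM (SD, n = 4 each, limma adjusted p = 0.0985). Interferon-stimulated genes (0 of 26, also adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.654 with an estimated correlation) were higher too. Bst2, the antiviral tetherin, was at 55.1 ± 8.86 and 77.7 ± 16.7 FPKM (SD, n = 4 each, limma adjusted p = 0.0713). In the glucocorticoid-responsive list, Errfi1, a feedback inhibitor of the EGF receptor, rose (0.42, SE 0.10) and 17 of 18 did not pass, also adjusted over the list alone (camera adjusted p = 2.04e-04, adjusted p = 0.507 with an estimated correlation). The clock gene Per1 was at 14.7 ± 2.26 and 24.2 ± 2.53 FPKM (SD, n = 4 each, limma adjusted p = 0.0807). The pan-neuronal score was 0.64 lower in the same libraries. With it as a covariate the cytokine call ended (mean 0.196 to 0.145, adjusted p = 0.494), and the means of the antigen presentation, interferon and macrophage lists went from 0.327 to 0.51, 0.229 to 0.347 and 0.333 to 0.22 (adjusted p = 0.0251, 0.0046 and 0.0495). With array weights the antigen presentation and cytokine calls ended (0.0541 and 0.0711). These lists also moved beside a neutrophil score of 0.40 ± 0.67 and a skeletal muscle score of 0.38 ± 1.04 in cisplatin libraries (SD, n = 4). A difference of these 2 scores from vehicle was not resolved (exact permutation p = 0.371 and 0.543), so a contribution of such cells is not excluded. Cisplatin replicate 4 was highest in its group for the neutrophil (1.23), macrophage (0.6) and interferon (0.65) scores. The cytokine call of camera ended without vehicle replicate 2 (adjusted p = 0.104), vehicle replicate 3 (0.0955) or cisplatin replicate 4 (0.131), antigen presentation without vehicle replicate 3 (0.0955), cisplatin replicate 2 (0.0514) or cisplatin replicate 4 (0.156), and interferon without cisplatin replicate 4 (0.202). The mean of the interferon list, 0.229, was 0.087 there and 0.345 without cisplatin replicate 3. The 3 gene calls ended without vehicle replicate 2 or cisplatin replicate 4, where 3 and 0 genes passed. Of the 34 lists tested 16 passed, and the 18 that did not had camera adjusted p of 0.0574 or more.

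Cdkn1a, the cell cycle inhibitor p21 that DNA damage induces, rose from 4.72 ± 1.05 to 9.45 ± 2.09 FPKM with cisplatin (SD, n = 4 each, log2 change 0.93, SE 0.23) and was among the largest rises. Abcb1b, a drug efflux pump, rose by 0.98 (SE 0.23) and Rgs1, a regulator of G protein signalling, by 0.97 (SE 0.22). Other large rises were those of Cldn22, a claudin (0.89, SE 0.19), Apold1, an early response gene of endothelium (0.85, SE 0.16), and Exosc3, a subunit of the RNA exosome (0.78, SE 0.15). Prok2, a secreted prokineticin, was listed at 0 in all 4 vehicle libraries and at 1.51, 0.98, 0.52 and 1.36 FPKM in cisplatin libraries. The largest falls included Creg2 (-1.05, SE 0.25), Ldoc1 (-1.02, SE 0.17), Gdap1l1 (-1.02, SE 0.21), Apoc3, an apolipoprotein (-1.00, SE 0.24), and Trnp1, a nuclear protein (64.4 ± 9.16 to 32.1 ± 1.79 FPKM, -0.98, SE 0.12). Of 32 p53 target and DNA damage genes, Cdkn1a, Xpc, a sensor of DNA lesions (0.24, SE 0.066), and Sesn1, a stress-induced sestrin (0.20, SE 0.045), rose and Zmat3 fell (-0.32, SE 0.063). The other 28 did not pass, adjusted over the list alone 3 rose and 1 fell, and the list did not pass (camera adjusted p = 0.113, adjusted p = 0.51 with an estimated correlation). Among 26 genes of sphingosine 1-phosphate metabolism and signalling, Sgpp2, a sphingosine 1-phosphate phosphatase, fell from 22.5 ± 2.49 to 12.8 ± 2.54 FPKM (-0.81, SE 0.14), Asah2, a ceramidase, fell (-0.51, SE 0.11) and Acer2, another ceramidase, rose (0.42, SE 0.10). The other 23 did not pass, adjusted over the list alone 4 fell and 3 rose, and the list did not pass (camera adjusted p = 0.338, adjusted p = 0.654 with an estimated correlation). Over cisplatin versus vehicle and CYM-5478 versus cisplatin together, 5 calls fell in this list, 16 under TPM. All gene calls of this paragraph ended without vehicle replicate 2 or cisplatin replicate 4, where 3 and 0 genes passed. The 5 calls became 2 without vehicle replicate 1, vehicle replicate 2 or cisplatin replicate 1, 8 without cisplatin replicate 2, 0 without cisplatin replicate 4 and 3 without CYM-5478 replicate 4.

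Neuronal genes were higher in rats given CYM-5478 with cisplatin than in rats given cisplatin alone. This comparison asks what the S1P2 agonist changed in rats given cisplatin. Tubb3 rose from 504 ± 98.8 to 799 ± 80.6 FPKM (SD, n = 4 each, log2 change 0.68, SE 0.15). Map2, a microtubule protein of dendrites, rose from 30.5 ± 5.98 to 46.7 ± 6.13 (0.62, SE 0.14), Pou4f1 by 0.65 (SE 0.13) and Eno2 by 0.48 (SE 0.11). Calca, the precursor of calcitonin gene-related peptide in pain-sensing neurons, rose from 230 ± 31.3 to 405 ± 77.7 FPKM (0.81, SE 0.14). Trpa1 rose by 0.70 (SE 0.10) and Gfra3, the artemin co-receptor, by 0.84 (SE 0.15). Of 18 pan-neuronal genes 8 rose, 0 fell and 10 did not pass, with 18 higher adjusted over the list alone (camera adjusted p = 2.67e-11, adjusted p = 0.516 with an estimated correlation). Nociceptor markers had 11 of 22 higher, 0 lower and 16 higher adjusted over the list alone (camera adjusted p = 2.67e-11, adjusted p = 0.516 with an estimated correlation). With the pan-neuronal score as a covariate the mean of the nociceptor list went from 0.54 to 0.154 (adjusted p = 2.82e-04). In all, 941 genes passed limma's test, 759 higher and 182 lower (80.7% higher, smallest adjusted p 0.0395), and under TPM 2545 did, 2497 higher and 48 lower (98.1% higher). Libraries of the 2 groups did not overlap for 16.1% of genes, against 2.86% by chance. The count was 0 without vehicle replicate 1, cisplatin replicate 1, cisplatin replicate 4 or CYM-5478 replicate 2, 3 or 4 (3011 to 4031 genes at an unadjusted p under 0.05). Vehicle replicate 1 is in neither group compared and enters only through the shared fit, and without it the smallest adjusted p was 0.0535. The count was 436 without vehicle replicate 3, 593 without vehicle replicate 4, 2 with no filter on low genes and 452 with array weights. Limma called 0 genes with the 8 libraries of the 2 groups alone (4009 at an unadjusted p under 0.05). It also called 0 with the title numbers as a block (3600). The same held for 2 alternatives chosen after seeing the data, the pan-neuronal score as a covariate (772) and leaving out CYM-5478 replicates 2 and 3 (2068). All 37 called genes named for this comparison lost their call without any 1 of these 6 libraries, and leaving out any other ended the call of 2 to 15 of them. None of the 37 turned in sign.

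**Figure D2:**
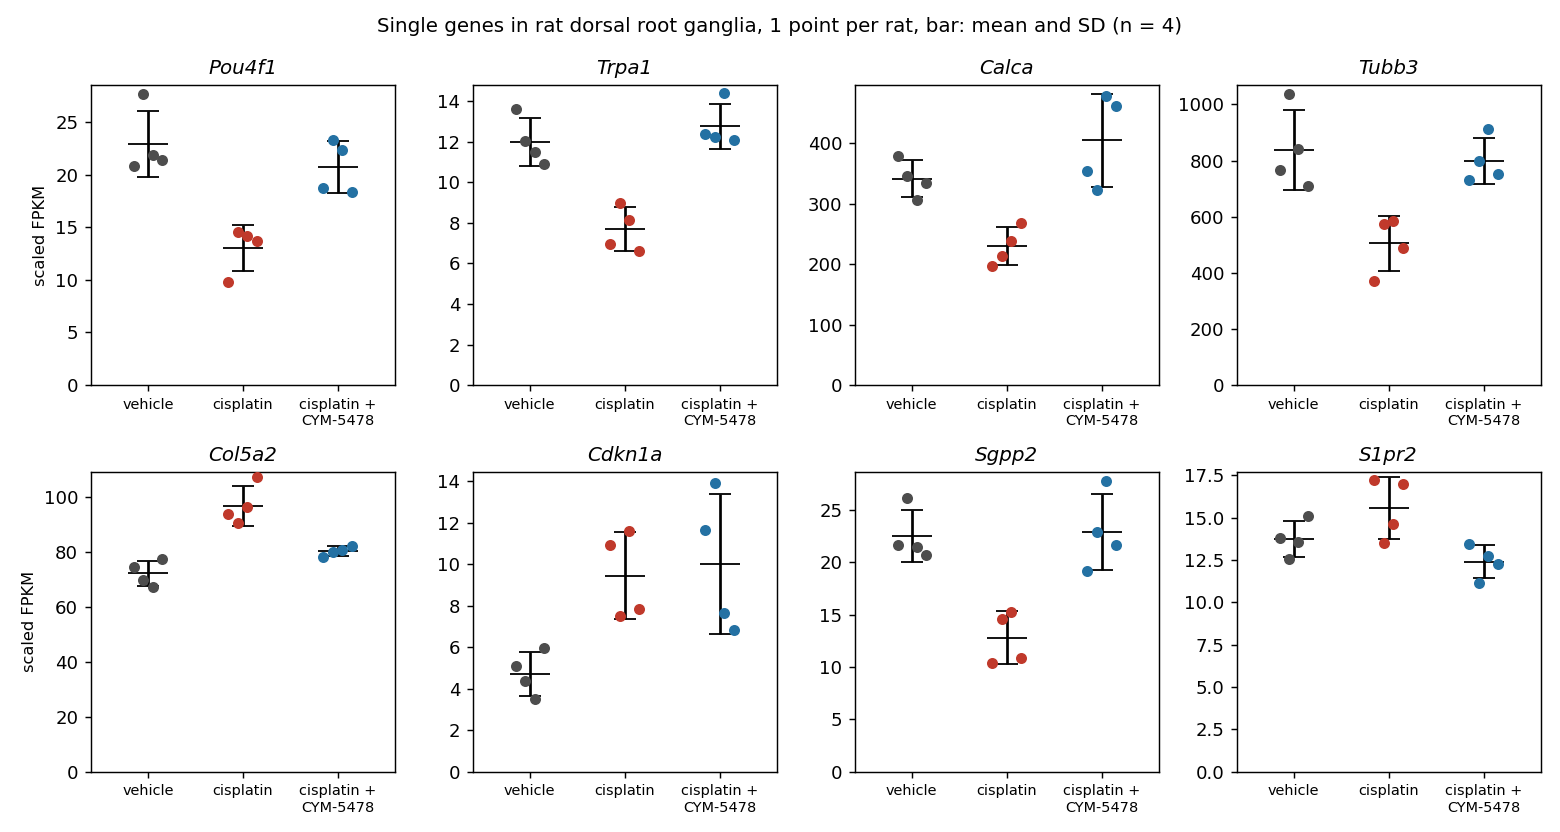
Scaled FPKM of 8 genes in each of the 12 libraries (y axis: FPKM from 0, x axis: treatment group, points: rats, bars: mean and SD, n = 4). Tubb3 averaged 838 in vehicle, 504 in cisplatin and 799 with CYM-5478, Cdkn1a 4.72, 9.45 and 10.0, and S1pr2 13.7, 15.6 and 12.4.

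Genes of other neuronal groups and channels also rose with CYM-5478. The largest rises included Kcng1 (log2 change 0.96, SE 0.13) and Kcnh6 (0.90, SE 0.18), subunits of potassium channels. Atp6ap1l (0.95, SE 0.24), Gdap1l1 (0.91, SE 0.21), Fstl5, a secreted glycoprotein (0.90, SE 0.17), and Tyrp1, known from melanin synthesis, also rose (Tyrp1 39.1 ± 7.92 to 71.3 ± 7.41 FPKM, SD, n = 4 each). Scn8a (0.67, SE 0.17), Kcnc1 (0.61, SE 0.16) and Ntrk2 (0.36, SE 0.086) were the 3 of 20 mechanoreceptor markers that rose. The other 17 did not pass and 5 rose adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.561 with an estimated correlation). Nerve injury genes had 5 of 21 higher, 0 lower and 7 higher adjusted over the list alone, but did not pass as a list (camera adjusted p = 0.0715, adjusted p = 0.561 with an estimated correlation). Among them, Adcyap1, a neuropeptide induced in injured neurons, rose by 0.70 (SE 0.15), Cacna2d1 by 0.51 (SE 0.095) and Lifr by 0.33 (SE 0.082). Hsp90aa1 (0.41, SE 0.10), Bag3 (0.47, SE 0.11) and Hspb1 (0.47, SE 0.12) rose out of 10 heat shock genes, 7 did not pass, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.00723, adjusted p = 0.516 with an estimated correlation). Atp5g1 rose by 0.34 (SE 0.082), 1 of 28 nuclear-encoded oxidative phosphorylation genes (5 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.561 with an estimated correlation). Of 13 satellite glia markers Aldoc rose (0.51, SE 0.11), 12 did not pass and 3 rose adjusted over the list alone, and the list did not pass (camera adjusted p = 0.376, adjusted p = 0.676 with an estimated correlation). Kcnj10 was at 11.8 ± 1.14 and 14.7 ± 1.39 FPKM (SD, n = 4 each, limma adjusted p = 0.0558). Pan-neuronal scores were 0.60 higher in these CYM-5478 libraries (-0.04 ± 0.19 against -0.64 ± 0.32, SD, n = 4 each). With that score as a covariate the mechanoreceptor, heat shock and oxidative phosphorylation calls ended, with means from 0.212 to -0.086 (adjusted p = 0.323), 0.196 to 0.041 (0.26) and 0.113 to -0.058 (0.0624). Without cisplatin replicate 4 the mechanoreceptor adjusted p was 0.0614. Without cisplatin replicate 1 the means of the mechanoreceptor and oxidative phosphorylation lists went from 0.212 to 0.141 and from 0.113 to 0.072, and 0 genes passed without vehicle replicate 1, cisplatin replicate 1 or 4, or CYM-5478 replicate 2, 3 or 4.

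Myelin, connective tissue and vessel genes were lower as lists with CYM-5478 than with cisplatin alone, by camera at its preset correlation. Exact permutation p of the list scores was 0.0571 for myelin, 0.0286 for matrix and 0.0571 for endothelial genes. No list of this comparison passed the rotation test (lowest adjusted p 0.0641). Ncmap, a protein of peripheral myelin, fell from 2250 ± 330 to 1390 ± 306 FPKM (SD, n = 4 each, log2 change -0.71, SE 0.17). It was the 1 of 22 myelinating Schwann cell genes past the threshold, and 5 fell adjusted over the list alone (camera adjusted p = 9.74e-08, adjusted p = 0.516 with an estimated correlation). Pmp2, the myelin fatty acid binding protein, was at 1070 ± 294 and 624 ± 250 FPKM (SD, n = 4 each, limma adjusted p = 0.0837). Col5a2 (-0.27, SE 0.060) and Pdgfra, the growth factor receptor of fibroblasts (-0.35, SE 0.080), fell out of 20 matrix genes, 18 did not pass and 9 fell adjusted over the list alone (camera adjusted p = 2.12e-06, adjusted p = 0.516 with an estimated correlation). Cldn5 fell (-0.39, SE 0.091), with 15 of 16 endothelial markers not past the threshold and 3 lower adjusted over the list alone (camera adjusted p = 1.41e-04, adjusted p = 0.516 with an estimated correlation). The largest falls included Cysltr1, a leukotriene receptor (-0.81, SE 0.19), Foxs1, a forkhead factor (-0.71, SE 0.12), Lamp3, a lysosomal membrane protein (-0.67, SE 0.13), Lect1, a chondromodulin (-0.64, SE 0.13), and the transcription factors Tbx18 (-0.63, SE 0.12) and Sox9 (-0.61, SE 0.15). Ribosomal protein genes were lower as a list, with 0 of 27 past the threshold by themselves and 3 lower adjusted over the list alone (camera adjusted p = 9.74e-08, adjusted p = 0.516 with an estimated correlation). So were mitochondrially encoded genes (0 of 11, also adjusted over the list alone, camera adjusted p = 6.60e-04, adjusted p = 0.561 with an estimated correlation, 0.664 after quantile normalization). Under quantile normalization their mean went from -0.375 to -0.067. Rpl5 was at 424 ± 18.9 and 369 ± 21.4 FPKM (SD, n = 4 each, limma adjusted p = 0.0555), and Mt-nd4l, of complex I, at 4140 ± 875 and 2760 ± 428 (limma adjusted p = 0.0847). Pan-neuronal scores were 0.60 higher in the same libraries. With that score as a covariate the means of the myelin and endothelial lists went from -0.362 to -0.151 and from -0.252 to -0.147 (adjusted p = 0.0624 for each), which ended both calls. By limma 0 genes passed without vehicle replicate 1, cisplatin replicate 1 or 4, or CYM-5478 replicate 2, 3 or 4.

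Macrophage, cytokine and immediate early lists were lower with CYM-5478 by camera at its preset correlation, with none of their genes past the threshold of limma. Macrophage markers had 0 of 17 past it (camera adjusted p = 0.00723, adjusted p = 0.561 with an estimated correlation), cytokine genes 0 of 22 (camera adjusted p = 0.0146, adjusted p = 0.517 with an estimated correlation) and immediate early genes 0 of 18 (camera adjusted p = 0.00763, adjusted p = 0.561 with an estimated correlation). The counts adjusted over the list alone were also 0. Emr1, a surface marker of macrophages, was at 15.5 ± 1.76 FPKM in cisplatin and 12.4 ± 0.926 with CYM-5478 (SD, n = 4 each, limma adjusted p = 0.0784). Vcam1 was at 14.6 ± 0.718 and 12.1 ± 1.34 (limma adjusted p = 0.0847) and the activity-dependent gene Arc at 1.91 ± 0.13 and 1.28 ± 0.131 (limma adjusted p = 0.0725). In the sphingosine 1-phosphate list, Sgpp2 rose from 12.8 ± 2.54 to 22.9 ± 3.61 FPKM (0.82, SE 0.14) and Acer3, a ceramidase, fell (-0.37, SE 0.082). The other 24 of 26 did not pass, adjusted over the list alone 5 rose and 3 fell, and the list did not pass (camera adjusted p = 0.731, adjusted p = 0.929 with an estimated correlation). Of 32 p53 target genes Zmat3 rose (0.30, SE 0.063), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.322, adjusted p = 0.645 with an estimated correlation). Cdkn1a was at 9.45 ± 2.09 FPKM in cisplatin and 10.0 ± 3.36 with CYM-5478 (SD, n = 4 each, limma adjusted p = 0.924) and Atf3 at 11.6 ± 2.61 and 8.81 ± 1.51 (limma adjusted p = 0.17). Pan-neuronal scores were 0.60 higher in the same libraries. With that score as a covariate all 3 list calls ended, with means from -0.207 to -0.1 for macrophage (adjusted p = 0.29), -0.187 to -0.138 for cytokine (0.29) and -0.243 to 0.019 for immediate early genes (0.339). The immediate early call ended without cisplatin replicate 1 (adjusted p = 0.0603), and the macrophage and cytokine calls without cisplatin replicate 4 (0.1 and 0.0992), where the macrophage mean went from -0.207 to -0.115. Gene calls ended, with 0 genes past the threshold, without vehicle replicate 1, cisplatin replicate 1 or 4, or CYM-5478 replicate 2, 3 or 4. Of the 34 lists tested 14 passed, and the 20 that did not had camera adjusted p of 0.0715 or more.

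Most genes that passed for cisplatin against vehicle had the opposite sign for CYM-5478 with cisplatin against cisplatin, although the 2 comparisons share the 4 cisplatin libraries. Neuronal genes such as Tubb3, Pou4f1, Eno2, Trpa1 and Scn8a, and Sgpp2, passed in both comparisons, lower with cisplatin and then higher with CYM-5478, and Col5a2 and Cldn5 passed in both the opposite way. Of the 1794 genes called for cisplatin against vehicle, 1785 (99.5%) had the opposite sign in CYM-5478 with cisplatin against cisplatin, and 747 passed in both with opposite signs. Of these, 670 were lower then higher and 77 were higher then lower. None of the genes past both thresholds had the same sign (0 genes). The shared libraries alone tie these signs and make such counts large. Free of that sharing, genes called with 2 cisplatin libraries were followed in the change from the other 2 to CYM-5478, where 67.7% to 73.4% of all genes had the opposite sign. Of the genes called, 1564 of 1648 (94.9%) had it for replicates 1 and 4, 233 of 263 (88.6%) for 2 and 4, 9 of 11 for 3 and 4, 8 of 9 for 1 and 2, and 0 of 1 for 2 and 3. For replicates 1 and 3 limma called 0 genes, with 3858 at an unadjusted p under 0.05. Over all genes the log2 changes had r = -0.74 and covariance -0.057, against a mean r of -0.50 and covariance of -0.0253 (-0.0464 to 0.01) in 100 simulations with unchanged groups. The difference of covariances was -0.0318. A mean covariance of -0.0345 was left when each comparison used 2 cisplatin libraries that the other did not (r from -0.39 to -0.30 over 6 splits). Both values take the spread between libraries out of the same covariance. Their closeness follows largely from how they were made and adds nothing. The 747 became 0 without vehicle replicate 1, cisplatin replicate 1 or 4, or CYM-5478 replicate 2, 3 or 4. Limma called 0 genes in 1 or both comparisons there, with 3011 to 4082 at an unadjusted p under 0.05. It became 1 without vehicle replicate 2, 323 without vehicle replicate 3 and 477 without vehicle replicate 4. Under TPM it was 2179, with array weights 365 and with no filter 1. It was 0 with fits of 8 libraries, the title numbers as a block, the pan-neuronal score as a covariate and without CYM-5478 replicates 2 and 3. There limma called 0 genes in 1 or both comparisons (772 to 4009 at an unadjusted p under 0.05).

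Ganglia of rats given cisplatin with CYM-5478 had a mean pan-neuronal score of -0.04, against 0 in vehicle rats. This comparison asks what remained different under both drugs. Limma called 0 of 16753 genes (970 at an unadjusted p under 0.05, where chance gives 838, smallest adjusted p 0.631), and a fit of these 8 libraries alone called 1. Libraries did not overlap for 3.45% of genes, against 2.86% by chance. Cdkn1a was at 4.72 ± 1.05 FPKM in vehicle and 10.0 ± 3.36 with both drugs (SD, n = 4 each, log2 difference 0.98, SE 0.23, limma adjusted p = 0.697). Abcb1b was at 0.383 ± 0.2 and 1.32 ± 0.55, Cldn22 at 2.07 ± 0.394 and 4.20 ± 1.15, and Apold1 at 4.03 ± 0.849 and 6.68 ± 1.16, each not past the threshold. Lower values, also not past it, were those of Irak4, a kinase of Toll-like receptor signalling (4.72 ± 0.239 and 2.80 ± 0.210), Edn1, the vasoconstrictor endothelin (3.01 ± 0.444 and 1.22 ± 0.243), and Ccdc71l (7.37 ± 1.02 and 2.92 ± 0.619 FPKM). Nrarp, a feedback inhibitor of Notch, was at 7.93 ± 0.575 and 5.49 ± 0.318 and Marcks, a substrate of protein kinase C, at 143 ± 12.3 and 102 ± 6.29. Foxs1 (29.7 ± 2.52 and 20 ± 3.81) and Shisa9, an auxiliary subunit of AMPA receptors, did not pass either (Shisa9 4.44 ± 0.981 and 2.46 ± 0.364 FPKM, SD, n = 4 each). Xpc was at 7.58 ± 0.346 and 8.53 ± 0.226 FPKM, Sesn1 at 16.7 ± 0.533 and 17.9 ± 0.366, and Acer2 at 3.69 ± 0.373 and 4.52 ± 0.715. Spns2, a sphingosine 1-phosphate exporter, was at 8.64 ± 0.628 and 7.65 ± 0.146 (limma adjusted p = 0.84 to 0.863, n = 4 each). The count was 2 without CYM-5478 replicate 2.

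Hormone-responsive and interferon genes were higher as lists under both drugs than in vehicle, by camera at its preset correlation. Neither list passed the rotation test (adjusted p = 0.639 and 0.928). Camera called 3 lists in this comparison, where other splits of the same libraries gave a median of 9. Glucocorticoid-responsive genes had 0 of 18 past the threshold and 3 higher adjusted over the list alone (median log2 difference 0.30, camera adjusted p = 1.10e-06, adjusted p = 0.62 with an estimated correlation). Per1 was at 14.7 ± 2.26 FPKM in vehicle and 30.5 ± 11.8 with both drugs and Fkbp5, a co-chaperone of steroid receptors, at 9.12 ± 1.83 and 14.8 ± 3.68. Klf9, a transcription factor, was at 36.8 ± 3.77 and 51.4 ± 9.88 and the kinase gene Map3k6 at 1.36 ± 0.137 and 2.05 ± 0.617 (SD, n = 4 each, limma adjusted p of the 4 genes 0.697 to 0.84). Interferon-stimulated genes had 0 of 26 past it, also adjusted over the list alone (median 0.32, camera adjusted p = 1.10e-06, adjusted p = 0.918 with an estimated correlation). Ddx58, the viral RNA sensor RIG-I, was at 4.83 ± 0.544 and 7.54 ± 2.23 FPKM, Ifit2, another antiviral gene, at 8.07 ± 1.19 and 11.8 ± 4.04, and Bst2 at 55.1 ± 8.86 and 69.8 ± 12.1 (SD, n = 4 each, limma adjusted p = 0.823 to 0.863). Interferon scores of the 4 rats ran from -0.12 in CYM-5478 replicate 2 to 0.92 in replicate 3, and without replicate 3 the mean log2 difference of the list fell from 0.315 to 0.11 (camera adjusted p = 0.0486). Proliferation genes had 0 of 24 past it, also adjusted over the list alone (median 0.19, camera adjusted p = 0.03, adjusted p = 0.918 with an estimated correlation). Pcna, the DNA replication clamp, was at 32.4 ± 1.34 and 37 ± 3.6 FPKM and Kif20a, a mitotic kinesin, at 1.89 ± 0.474 and 2.53 ± 0.866 (SD, n = 4 each, limma adjusted p = 0.84 and 0.924). This camera call ended without vehicle replicate 1 (0.0849), 2 (0.223) or 4 (0.166) or CYM-5478 replicate 1 (0.156), and turned in sign without CYM-5478 replicate 2 (mean log2 difference -0.05, adjusted p = 0.887, against 0.206 with all libraries). It also ended with a filter of 2 FPKM (0.0665), the 8 libraries alone (0.0547), the pan-neuronal score as a covariate (0.0681) and the title numbers as a block (0.67, mean 0.062). The mean was 0.135 without CYM-5478 replicate 1, 0.453 without replicate 3 and 0.374 without vehicle replicate 3. The number of lists past the threshold, 3, became 10 and 6 without vehicle replicates 1 and 4, 5 and 8 without cisplatin replicates 2 and 4, and 6, 11 and 8 without CYM-5478 replicates 1, 3 and 4. Pan-neuronal scores were -0.04 ± 0.19 with both drugs and 0 ± 0.16 in vehicle (SD, n = 4 each, exact permutation p = 0.771), and the neutrophil score was 0.22 ± 1.32.

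Receptors for sphingosine 1-phosphate, including the S1P2 receptor on which CYM-5478 acts, passed the threshold over all tested genes in none of the 3 comparisons. S1pr2 was at 13.7 ± 1.04 FPKM in vehicle, 15.6 ± 1.81 in cisplatin and 12.4 ± 0.969 with CYM-5478 (SD, n = 4 each, limma adjusted p = 0.23 for cisplatin against vehicle, 0.0593 for CYM-5478 against cisplatin and 0.924 for CYM-5478 against vehicle). Adjusted over the sphingosine 1-phosphate list alone, S1pr2 was among the genes that fell with CYM-5478 against cisplatin. Without cisplatin replicate 2 its log2 difference for CYM-5478 against cisplatin, -0.38, had an adjusted p of 0.0391 over all genes. Over all alternatives run the adjusted p of S1pr2 went from 0.0193 to 0.996. S1pr3, the most abundant of the family here, was at 31.5 ± 5.57, 27.8 ± 4.04 and 28.8 ± 3.23 FPKM in the same order. S1pr1, a receptor of vessels and lymphocytes, was at 7.87 ± 1.5, 9.38 ± 0.692 and 8.27 ± 0.879 and S1pr4, found in blood cells, at 1.74 ± 0.633, 2.35 ± 0.962 and 1.86 ± 0.898 (SD, n = 4 each, limma adjusted p of the 3 = 0.194 to 0.999). S1pr5, a receptor of oligodendrocytes and natural killer cells, had a mean of 0.382 FPKM over the 12 libraries and was not tested. Atf3 was at 9.72 ± 0.942 FPKM in vehicle and 8.81 ± 1.51 with both drugs (SD, n = 4 each, limma adjusted p = 0.98).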

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

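The 7 tests of explanations and the splits for the 3 counts of genes were chosen after the results were seen, and the splits for lists, for opposite directions and for both cisplatin groups were set before. In 22 of 377 groups of 4 libraries 1 library stood far from the other 3, where chance gives about 18.8.

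In vehicle, replicate 2 was apart for Pou4f1 (27.7 FPKM, others 20.8 to 21.9), Cox5a (216, others 183 to 188), Sgpp2 (26.2, others 20.7 to 21.6), Marcks (125, others 148 to 151) and the nuclear oxidative phosphorylation score (0.103, others -0.0431 to -0.0288). Vehicle replicate 3 was apart for S1pr4 (2.68 FPKM, others 1.34 to 1.56), Klf9 (31.2, others 38.5 to 38.9), the proliferation score (0.5, others -0.194 to -0.131) and the red blood cell score (0.652, others -0.281 to -0.134). Cisplatin replicate 1 was low for Hsp90aa1 (326 FPKM, others 402 to 413), Bag3 (26.6, others 34.7 to 36), the heat shock score (-0.281, others -0.125 to -0.11) and the oxidative phosphorylation score (-0.237, others -0.0737 to -0.0408). Ntrk2 was high in cisplatin replicate 3 (18.3 FPKM, others 15 to 15.6), and Arc (2.1 FPKM, others 1.82 to 1.87) and the cytokine score (0.35, others 0.136 to 0.155) in cisplatin replicate 4. With CYM-5478, replicate 3 was apart for Trpa1 (14.4 FPKM, others 12.1 to 12.4), Bst2 (87.8, others 62.4 to 64.5) and the mechanoreceptor score (-0.0157, others -0.149 to -0.132). Glul was low in CYM-5478 replicate 1 (208 FPKM, others 222 to 224), Apold1 high in replicate 4 (8.41, others 5.89 to 6.21), and the FPKM sum high in replicate 2 (626 in units of 1000 FPKM, others 596 to 600).

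Neuronal genes were lower with cisplatin and higher with CYM-5478 added, while Schwann cell, matrix, endothelial and macrophage lists went the other way. Fewer neurons in cisplatin than in vehicle, and more with CYM-5478 than in cisplatin, with every other cell type in its usual proportion, would move all other cell types alike. The mean score of these 4 lists minus the satellite glia score changed by 0.33 (exact permutation p = 0.0286) and -0.37 (exact permutation p = 0.0571), but 6 of the 13 satellite glia markers were higher and 7 lower with cisplatin (quartiles -0.34 and 0.20), which keeps this explanation open. A different mix of ganglion and attached nerve in the dissected samples may account for the pattern and stays open, as within groups the pan-neuronal and Schwann cell scores had r = -0.46 (permutation p = 0.145, adjusted p = 0.217 over 3 relations), rho = -0.53 (p = 0.131) and r = -0.26 without the 2 libraries farthest from the median. A change of transcription inside neurons was not tested. Such a change and a change in the number of neurons would both be biological, unlike a different dissection mix. These explanations cannot be told apart because cell numbers and dissection could differ between groups.

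Proliferation genes moved together between libraries, from 0.5 in vehicle replicate 3 against -0.194 to -0.131 in the other vehicle libraries. Blood-forming cells in some samples are a candidate source, since within groups the neutrophil precursor score and the proliferation score had r = 0.96 and rho = 0.95 (permutation p = 0.000289 for each, adjusted p = 0.000868), and r = 0.91 without the 2 farthest libraries. The lists share 0 genes, S100a8 ranged from 121 to 1265 FPKM, S100a9 from 65.4 to 775 and Hba1 from 3834 to 20700, and 12 of the 14 neutrophil genes were above 0.5 FPKM in every library. An effect of cisplatin on dividing cells stays open, with a score 0.22 (SE 0.23) higher in both cisplatin groups than in vehicle (exact permutation p = 0.406).

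Cdkn1a had a higher mean in both cisplatin groups than in vehicle, but did not pass the threshold in that comparison (log2 difference 0.95, limma adjusted p = 0.135). The values went against a p53 response in which the listed targets rise on average by 0.48 or more, a mark set after the results were seen. The other 31 targets had a mean of 0.04 (18 above 0). The upper limit of 0.10 comes from the spread over genes and leaves out that between rats. A weaker response or one of a few targets is not excluded. A shared stress hormone response stays open, with a within-group r of -0.06 between Cdkn1a and the glucocorticoid score (permutation p = 0.894, rho = 0.06, p = 0.863, r = -0.29 without the 2 farthest libraries). No technical explanation was tested for it.

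For the 1794 genes of cisplatin against vehicle, 1 of the 35 splits, the real one, gave as many and the highest other gave 2. The 941 genes of CYM-5478 with cisplatin against cisplatin stood likewise (1 of 35, highest other 1). This argues against chance only as far as 35 splits can. The splits were chosen after the results were seen, and the 2 comparisons share the cisplatin libraries. For the 747 genes of opposite direction 1 of 100 drawn splits, the real one, gave as many (highest other 5), which rests on the same calls as these 2 counts and adds nothing to them. Chance cannot be excluded for the number of lists in any comparison, with 7 of 35 splits giving 16 or more lists for cisplatin against vehicle (highest other 19), 9 of 35 giving 14 or more for CYM-5478 against cisplatin (highest other 20) and 35 of 35 giving 3 or more for CYM-5478 against vehicle (highest other 19). For CYM-5478 against vehicle limma called 0 genes (970 at an unadjusted p under 0.05, highest other split 1), so all 35 splits give as many whatever the data, and the splits say nothing about chance there. Chance cannot be excluded for the 1 gene of both cisplatin groups against vehicle, where 16 of 100 splits gave as many. In that comparison the highest other split gave 2296 genes. Which libraries that split set apart was not examined, so the source of this count is unknown.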

How the results depend on the processing

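The rotation test, the pan-neuronal covariate and the fits without pairs of libraries were tests chosen after the results were seen. Of 1533 values of the 53 genes called for cisplatin against vehicle, 1152 kept direction and call, 380 lost the call and 1 turned. Of 1070 values of the 37 genes called for CYM-5478 with cisplatin against cisplatin, 584 kept both and 486 lost the call. Lists kept both in 427 of 480, 375 of 420 and 75 of 90 values in the 3 comparisons. Absolute depth is unknown, so what it limits was not measured. The smallest adjusted p of the first 2 comparisons were 0.0124 and 0.0395. Except where stated, the cause was not tested.

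Leaving out each library in turn, with fewer samples in the fit, gave 0 to 1846 genes for cisplatin against vehicle, 0 to 1088 for CYM-5478 against cisplatin, 0 to 2 for CYM-5478 against vehicle, and 0 to 838 genes of opposite direction. Calls among sphingosine 1-phosphate genes ranged from 0 to 8 and lists for CYM-5478 against vehicle from 2 to 11. The log2 difference ranged for CYM-5478 against vehicle from -0.189 to 0.288 in S1pr4, -0.012 to 0.176 in S1pr1, -0.024 to 0.016 in the sphingosine 1-phosphate list and -0.052 to 0.453 in the proliferation list. For CYM-5478 against cisplatin it ranged from -0.123 to 0.203 in Cdkn1a and -0.001 to 0.148 in S1pr3.

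The lists past the threshold, 16, 14 and 3, became 0, 0 and 0 with an estimated correlation and 7, 0 and 0 with the rotation test, where 6 of the 16 kept their call and the repair Schwann cell list, not among the 16, passed (adjusted p = 0.0388). With no filter, which tests more genes, 2 genes passed for CYM-5478 against cisplatin, 1 in opposite directions and 3 calls among sphingosine 1-phosphate genes. TPM gave 3274 and 2545 genes, 2179 of opposite direction and 16 sphingosine 1-phosphate calls. Quantile normalization turned S1pr4 for CYM-5478 against vehicle to -0.001. Array weights gave 452 genes for CYM-5478 against cisplatin and 365 of opposite direction, and turned Cdkn1a there to -0.005 and the sphingosine 1-phosphate list for CYM-5478 against vehicle to 0.006. Fits of 8 libraries gave 1019, 0 and 1 genes (limma, 4009 at an unadjusted p under 0.05 where it called 0), 0 of opposite direction and 3 sphingosine 1-phosphate calls.

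With the pan-neuronal score as a covariate limma called 0 genes for cisplatin against vehicle and 0 for CYM-5478 against cisplatin, 0 of opposite direction and 0 sphingosine 1-phosphate calls, and 7 lists for CYM-5478 against cisplatin. The median change of the called genes went from 0.43 (SE 0.10) to 0.16 (SE 0.11) and from 0.47 (SE 0.11) to 0.15 (SE 0.10), so the calls ended because the changes became smaller. The score itself was lower in all 4 cisplatin libraries (-1.08 to -0.406) than in any other library (-0.205 to 0.233). The covariate therefore takes out part of any difference between cisplatin and the other groups, and a call that it ended says nothing about the cause. Of the 16, 14 and 3 lists, 7, 4 and 2 kept direction and call, and 7, 7 and 1 lost the call without turning. The 7 and 7 include the pan-neuronal list, whose mean is set to 0 by its own score as covariate. The covariate turned these values for cisplatin against vehicle: heat shock 0.005, oxidative phosphorylation 0.082, S1pr4 -0.287, Atf3 -0.29, S1pr2 -0.08 and Hsp90aa1 0.001. For CYM-5478 against cisplatin it turned immediate early genes to 0.019, mechanoreceptor markers to -0.086, oxidative phosphorylation to -0.058, S1pr4 to 0.277 and Atf3 to 0.116, and for CYM-5478 against vehicle S1pr4 to -0.01. Without cisplatin replicates 2 and 3 S1pr3 for CYM-5478 against cisplatin was -0.003 and there were 8 sphingosine 1-phosphate calls. Without CYM-5478 replicates 2 and 3 limma called 0 genes for CYM-5478 against cisplatin (2068 at an unadjusted p under 0.05), 1 gene and 7 lists for CYM-5478 against vehicle, and 0 genes were of opposite direction. There Cdkn1a was -0.057 for CYM-5478 against cisplatin, and for CYM-5478 against vehicle the sphingosine 1-phosphate list was 0.028, S1pr3 0.005 and Atf3 0.044.

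As a replicate block, the description numbers gave 1881, 1304 and 0 genes in the 3 comparisons, 1074 of opposite direction and 16, 14 and 7 lists. The title numbers gave 0, 0 and 0 genes, 0 of opposite direction, 0 sphingosine 1-phosphate calls and 15, 14 and 6 lists, and turned Cdkn1a for CYM-5478 against cisplatin to -0.049 and, for CYM-5478 against vehicle, the sphingosine 1-phosphate list to 0.004 and S1pr4 to -0.077. The numbers gave no sign of paired samples, as residuals of libraries with the same number correlated at -0.28 to 0.18 for 12 pairs by description and -0.12 to 0.17 for 7 pairs by title.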

Other observations

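All tests of gene families and of both cisplatin groups against vehicle were chosen after the results were seen, apart from the splits for the latter.

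Many members of ion channel families fell with cisplatin, and some rose when CYM-5478 was added. The family tests took 14981 of the tested genes as background, of which 1261 (8.42%) fell with cisplatin. Of 79 potassium channel genes, 31 fell with cisplatin where 6.65 would by that share (Fisher's exact test, adjusted p = 1.78e-12 over 64 tests). With CYM-5478 added 18 rose where 3.83 would (Fisher's exact test, adjusted p = 6.40e-07). Kcnc1, a fast potassium channel, was in both. Their median log2 change was -0.42 and 0.42, with the same sign under all 4 scalings. GABA-A receptor subunits fell in 6 of 9 (expected 0.758, adjusted p = 1.89e-04) and vacuolar ATPase subunits, which acidify vesicles, in 9 of 16 (expected 1.35, adjusted p = 1.75e-05), while 4 of the 9 and 8 of the 16 family members rose with CYM-5478 added (adjusted p = 0.00279 and 4.26e-06). Sodium channels, with Scn8a, fell in 5 of 12 and calcium channels, with Cacna2d1, in 7 of 20 (adjusted p = 0.00714 and 0.00386). Ribosomal protein genes rose in 29 of 84 (expected 2.48, adjusted p = 7.24e-22) and collagen genes, with Col5a2 and Col6a1, in 8 of 40 (expected 1.18, adjusted p = 1.65e-04). With CYM-5478 added 6 of the 84 and 3 of the 40 family members fell (adjusted p = 0.00244 and 0.0318), and 1 of the 40, Col19a1, named after its values were seen, rose. The median change of each of these families kept its sign under no scaling, TPM and quantile normalization, but some became smaller. Ribosomal protein medians went from 0.27 to 0.15 under TPM and 0.13 under quantile normalization for cisplatin against vehicle, and from -0.20 to -0.09 and -0.12 for CYM-5478 against cisplatin. Collagen medians went from 0.29 to 0.18 and from -0.24 to -0.13 under TPM, which moved the median of all tested genes from 0.02 to -0.09 and from -0.02 to 0.08. The pan-neuronal score was 0.64 lower with cisplatin and 0.60 higher with CYM-5478 added in the same libraries, and with this score as a covariate limma called 0 genes in either comparison (1321 and 772 at an unadjusted p under 0.05). Genes of a family are not independent of each other, which this test assumes, and the calls of genes ended without vehicle replicate 2 or cisplatin replicate 4 (3 and 0 genes for cisplatin against vehicle). For CYM-5478 against cisplatin 0 genes were called by limma without vehicle replicate 1, cisplatin replicate 1 or 4, or CYM-5478 replicate 2, 3 or 4, with 3011 to 4031 at an unadjusted p under 0.05.

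With both cisplatin groups set against vehicle, limma called 1 gene, Nrarp, a feedback inhibitor of Notch (log2 difference -0.65, SE 0.073, adjusted p = 0.0265), with 2859 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 4 genes. It was 0 without vehicle replicate 1 or 3, cisplatin replicate 4, or CYM-5478 replicate 1, 3 or 4, 4 without cisplatin replicate 1 and 3 without CYM-5478 replicate 2.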
